A study of Penicillium oxalicum with 9 samples.

How the data were processed

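Gene expression was measured in mycelium of 3 Penicillium oxalicum strains, with 3 libraries per strain and 9 in all. Samples were grouped by the strain their labels give: wild type, crzA deletion or crzA recovery. All values came from 1 table of 9860 genes with a column per library, and each column was matched to its sample by name.

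The deposited values are FPKM, per the file headers, which means fragments per kilobase of gene scaled to the total of the library, and they are rounded to 2 decimals. Per the labels' protocols, the libraries were made by cutting cDNA with NlaIII and MmeI to obtain short tags (digital gene expression profiling). A tag library yields a fixed site per transcript and needs no division by gene length, so the protocol and the unit in the header do not match. The smallest step between low values differed from gene to gene. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. If values from tags were divided by gene length, levels of different genes in the same library cannot be compared as numbers of molecules, while fold changes of a gene between libraries would be altered by that division only through the pseudocount and the filter. Shares of summed FPKM in the report have the same limit.

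The number of reads per library is unknown, so no counting interval was computed. For 434 of 9305 eligible genes, values stepped in whole multiples of a gene-specific amount of at least 0.15 FPKM, within a tolerance of at most 0.2 reads. After each value was shifted at random by up to 10%, 0 genes did so. The median step was 0.257 FPKM and the largest 2.26. Ratios of these steps gave relative depths within 3.14% of the mean. The ratios were built from values near the lowest of each gene. A library at 2-fold lower depth, whose values are also whole multiples of the step, could therefore have gone unseen. Replicates were compared before averaging. Over low genes, recovery replicates 1 and 2 had a dispersion of 1.06 times that of read sampling (chi-square p = 0.222) and wild-type replicates 1 and 3 one of 1.12 (chi-square p = 0.0795), so neither pair could be told from read sampling there. Over 179 abundant genes, taking the largest step found as the value of a read, the median dispersion was at least 1.66 and 3.22 in these pairs, and the mean at least 4.40 and 10.7. All 9 libraries were counted as separate samples on the abundant genes.

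Genes with an FPKM of at least 1 in at least 3 of the 9 libraries were kept, 9099 in all, and 37 of the 9860 genes were at 0 in every library. Values were analysed as log2(FPKM + 1) with no further scaling. limma 3.58.1 in R 4.3.3 was fitted to all 9 libraries with 1 mean per strain and no covariates, followed by empirical Bayes moderation with trend and robust options. The 3 strain comparisons were tested two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Log2 changes have the standard error of limma, and means have the SD over 3 libraries. Genes called against both other strains with one sign were counted and set beside 100 simulations of unchanged groups and beside independent lists. The covariance of both sets of log2 changes was also computed with the deletion libraries split so that none entered both, which gave a mean of 5.27e-05 in the simulations. Summaries, permutations and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

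The test was tried on simulated values for the 9099 genes of the deletion and wild-type comparison, with 200 genes changed, in 10 draws. It recovered 59.9% of genes changed 2-fold and 95% of those changed 4-fold, 3.9% of its calls were false, and it made 0 calls in a comparison without changes. The simulated noise was normal, with the same spread in all 9 libraries and none standing apart. These rates therefore need not hold for the real libraries, whose spread was unequal. The test for runs of neighbouring genes was significant in 2 of 40 random orders and in 10 of 10 draws with planted runs.

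The reference table belongs to strain HP7-1 and carries other locus tags. It matched 0 of the locus numbers, so no gene was named. For that reason the 21 gene lists fixed before the data were examined, their camera tests, the cross-check of known loci and the check of crzA in each library were not made. The tests, the comparisons, the naming rule and the main alternatives were also fixed before the data were examined. The rule names at most 2 genes higher and 2 lower per comparison, where the file pairs no names. They are those with the largest log2 change past the threshold, with the 3 values of one strain all above or all below those of the other, and with a mean of at least 5 FPKM over the 9 libraries. Any other locus number was chosen after its values were seen. Alternatives covered pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, rescaling to TPM, quantile normalization, median centring, and limma without trend and robust options. They also covered a fit to the compared strains alone, the replicate number as a block, a test against a 1.5-fold change, an adjusted p under 0.01, and each library left out in turn. After the data were seen, 3 were added: both libraries that stood apart left out, limma array weights, and the most abundant gene left out with the rest rescaled.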

Results

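Messenger RNA levels were measured in mycelium of Penicillium oxalicum, a filamentous fungus that secretes enzymes breaking down plant polysaccharides. The series held 3 strains with 3 libraries each. These were the wild type, a strain with crzA deleted, and a strain with crzA put back, called the recovery strain here. CrzA is a zinc finger transcription factor of fungi that acts downstream of calcineurin, the calcium-activated phosphatase. The series title places the question in the part CrzA plays in fungal development and in the expression of cellulose-degrading genes. Mycelium was pre-cultured for 24 h at 30 °C and harvested 18 h after its transfer to a new medium, which held 2% starch by the medium label. The source labels of all 9 samples name glucose, whereas the medium, growth and design labels name starch, and the conflict was not settled. No label says whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

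The file listed 9860 genes by locus number, with a value in FPKM (fragments per kilobase of gene, scaled to library size) for each library. It paired no locus number with a gene name, and 0 of the numbers matched the reference table, which describes another strain. The level of crzA in the deletion and recovery libraries, which would check the labels, was therefore not analysed here, and neither were cellulase, amylase or developmental genes as groups. Summed FPKM ranged from 973798 to 1063502 per library. The number of reads per library was not given. Low values of 434 genes rose in whole steps, from which relative depth was estimated to lie within 3.14% of the mean in every library. This estimate could miss a 2-fold difference in depth. A total of 9099 genes reached an FPKM of at least 1 in at least 3 of the 9 libraries and were tested.

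The largest component of variance set the deletion strain apart from both other strains. Principal component 1 held 68% of the variance and placed the 3 deletion libraries at 64.1 to 71.9. Wild-type replicate 2 lay at -17.4, nearer the deletion libraries than the other wild-type and recovery libraries, which lay between -39.5 and -36.2. Principal component 2 held 13.6% and set wild-type replicates 1 and 3 (36.9 and 30.1) apart from wild-type replicate 2 (-15.4), which lay beside the recovery libraries (-20.0 to -13.9). Deletion replicate 2 (-23.0) also lay apart from deletion replicates 1 and 3 (14.9 and 9.51). Across the tested genes, which are not independent replicates, the log2 values of wild-type replicates 1 and 3 correlated at r = 0.993, and those of replicates 1 and 2 at r = 0.943. Wild-type replicate 2 correlated at 0.967 to 0.969 with the recovery libraries.

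**Figure D1:**
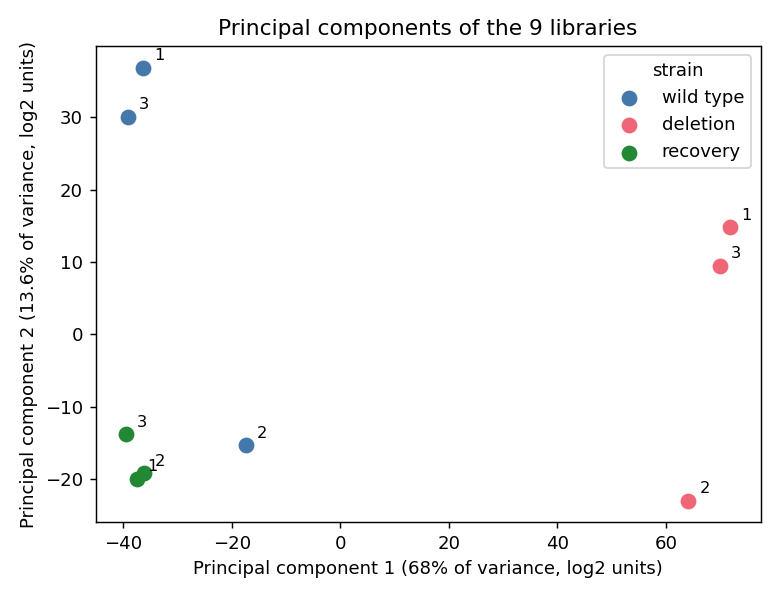
Principal components 1 and 2 of the log2(FPKM + 1) values of the tested genes, with 1 point per library, coloured by strain and numbered by replicate. The 3 deletion libraries lie at 64.1 or above on component 1. Wild-type replicate 2 lies beside the recovery libraries on component 2, but at -17.4 on component 1, nearer the deletion libraries than they do.

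The comparison of the deletion strain with the wild type addressed which transcripts differ when crzA is absent. The deletion strain had 1362 genes higher and 1012 lower than the wild type, 26.1% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). Of these, 614 were higher and 684 lower by at least 2-fold on the log2(FPKM + 1) scale, which understates the change of low genes. Large changes were mostly decreases, with 207 genes lower and 62 higher by at least 8-fold. The steepest falls under the rule for naming genes were those of PDE_09235 and PDE_09234. PDE_09235 went from 4621 ± 734 FPKM in the wild type to 7.20 ± 0.582 in the deletion strain (SD, n = 3 each), a log2 change of -9.13 ± 0.18 (SE, limma adjusted p = 1.13e-08). PDE_09234 went from 2812 ± 531 to 4.36 ± 1.20 FPKM, a log2 change of -9.04 ± 0.21 (limma adjusted p = 1.80e-08). The steepest rises were those of PDE_01233 and PDE_01199. PDE_01233 went from 0.523 ± 0.659 to 96.2 ± 13.9 FPKM, a log2 change of 6.07 ± 0.29 (limma adjusted p = 5.84e-07). The size of this change depended on the pseudocount because of the low wild-type values, at 7.81 with 0.1 and 4.19 with 5. PDE_01199 went from 13.2 ± 3.42 to 637 ± 127 FPKM, a log2 change of 5.51 ± 0.25 (limma adjusted p = 4.91e-07). With a pseudocount of 5 it was 5.14, above that of PDE_01233.

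The size of the change was also described by shares of summed FPKM. The sets of genes below were chosen by their change between the wild type and the deletion strain. Their shares in these strains therefore had to move and are no added support. PDE_09832, chosen after its values were seen, was the most abundant transcript of the file in the wild type and held 9.03% ± 0.461 of summed FPKM there (SD, n = 3). In the deletion strain it held 0.514% ± 0.0829, and in the recovery strain 10.5% ± 0.180. Its level was 94342 ± 3660 FPKM in the wild type and 5138 ± 1026 in the deletion strain, a log2 change of -4.22 ± 0.21 (limma adjusted p = 7.12e-07). The 614 genes higher by at least 2-fold together took 5.15% ± 0.826 of summed FPKM in the wild type and 18.0% ± 0.861 in the deletion strain. The 684 genes lower by at least 2-fold took 24.4% ± 2.77 in the wild type and 2.53% ± 0.137 in the deletion strain. Without PDE_09832 the latter shares were 15.4% ± 2.45 and 2.02% ± 0.0654. In the recovery strain the higher genes took 4.74% ± 0.0131 and the lower genes 25.1% ± 0.215. Recovery values did not enter the fold changes that chose these genes, but they entered the filter and the spread behind the adjusted p. The number of calls depended on which libraries were in the fit. A fit to these 2 strains alone, without the recovery libraries, gave 760 higher and 680 lower. The log2 changes stayed the same, so the counts moved through the estimate of spread and the number of libraries behind it. Log2 differences between libraries of a strain had an SD of 0.198 to 0.304 in the recovery strain. They had an SD of 0.245 to 0.715 in the wild type and 0.351 to 0.758 in the deletion strain. Without wild-type replicate 2 and deletion replicate 2, a choice made after seeing the data, 2599 genes were higher and 2319 lower. Leaving out deletion replicate 2 alone gave 2155 and 1601, leaving out wild-type replicate 3 gave 786 and 649, and leaving out wild-type replicate 1 gave 785 and 691.

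**Figure D2:**
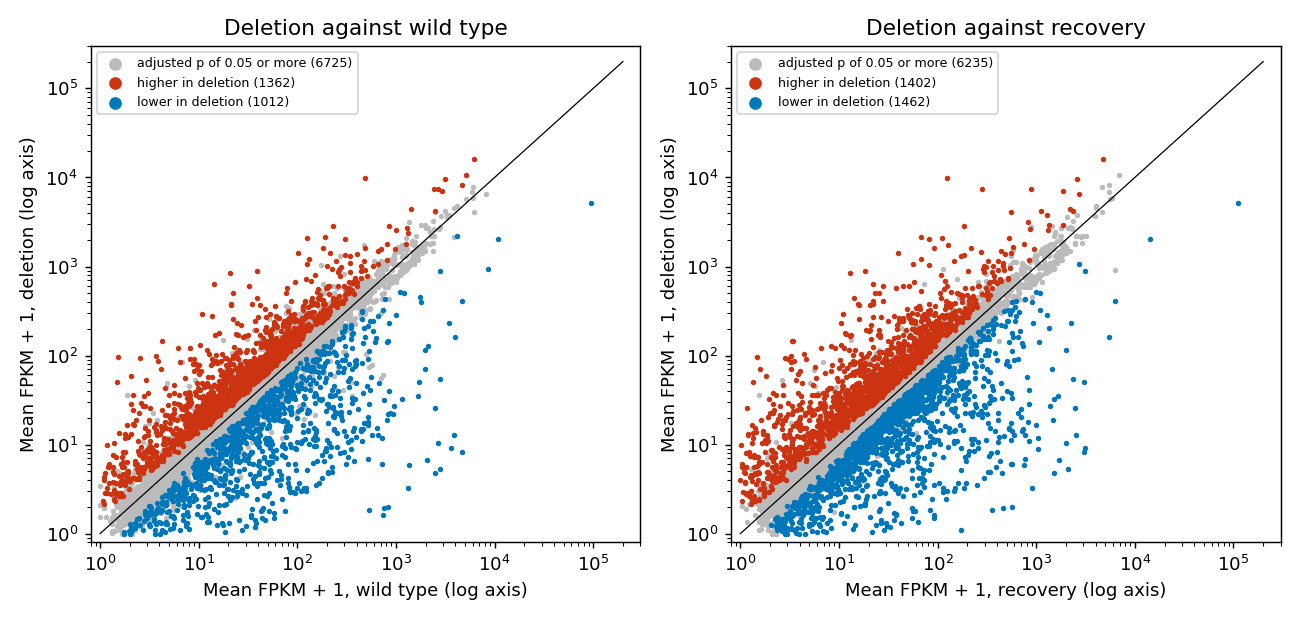
Mean FPKM + 1 of each tested gene in the deletion strain against the wild type (left) and against the recovery strain (right), on log axes, with 1 point per gene. Coloured points passed limma at an adjusted p under 0.05, 1362 higher and 1012 lower on the left and 1402 higher and 1462 lower on the right, and the blue point at the far right of each panel is PDE_09832.

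The comparison of the deletion strain with the recovery strain asked whether the changes were absent once crzA was put back. Here 1402 genes were higher and 1462 lower in the deletion strain, 31.5% of those tested (limma, adjusted p under 0.05). By at least 2-fold, 764 were higher and 799 lower. PDE_09234 and PDE_09235 again fell furthest under the naming rule. PDE_09234 stood at 2113 ± 256 FPKM in the recovery strain (SD, n = 3), so that its log2 change in the deletion strain was -8.64 ± 0.21 (limma adjusted p = 1.92e-08). PDE_09235 stood at 3048 ± 496 FPKM in the recovery strain, with a log2 change of -8.53 ± 0.18 (limma adjusted p = 1.02e-08). The steepest rises were those of PDE_01194 and PDE_01233. PDE_01194 reached 9806 ± 1188 FPKM in the deletion strain against 124 ± 38.0 in the recovery strain, a log2 change of 6.33 ± 0.89 (limma adjusted p = 0.000780). Its wild-type values were uneven, at 103, 1277 and 74.4 FPKM in replicates 1, 2 and 3. PDE_01233 stood at 0.490 ± 0.209 FPKM in the recovery strain, a log2 change of 6.03 ± 0.29 (limma adjusted p = 4.55e-07). With a pseudocount of 0.1 this change was 7.41, above the 6.35 of PDE_01194, and with a pseudocount of 5 it was 4.20. Without deletion replicate 2, 2063 genes were higher and 2234 lower. Without recovery replicate 1 the counts were 906 and 916, without recovery replicate 2 they were 883 and 943, and without recovery replicate 3 they were 926 and 1063.

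Most genes called against the wild type were also called against the recovery strain in the same direction. There were 1028 such genes higher and 851 lower in the deletion strain, 75.5% and 84.1% of those called against the wild type. Another 2 genes were called in both comparisons with opposite signs. Both comparisons use the same deletion libraries. Simulated unchanged groups set against shared libraries gave a mean overlap of 0.01 genes higher and 0 lower over 100 simulations, but unchanged groups yield almost no calls, so this value does not measure what sharing adds where genes do change. Independent lists of these sizes would share 209.9 and 162.6. With 3 deletion libraries no split leaves at least 2 in each part, so part of the excess in these counts may come from the shared libraries. Across genes, the log2 changes of both comparisons correlated at r = 0.914, where simulated unchanged groups gave 0.501. Their covariance was 1.11 against a simulated 0.0375, a difference of 1.07. With the deletion libraries split into 1 and 2, so that none entered both comparisons, a check added after seeing the data, the covariance had a mean of 1.04 over 6 splits, with 0.952 as the lowest. The overlap was 1689 higher and 1424 lower without deletion replicate 2, and 667 higher and 606 lower without wild-type replicate 3.

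The comparison of the recovery strain with the wild type asked how far the strain with crzA put back lay from the parent. It had 77 genes higher and 66 lower, 1.57% of those tested (limma, adjusted p under 0.05), and 1293 genes had an unadjusted p under 0.05. PDE_07655 stood at 169 ± 37.8 FPKM in the recovery strain and 8.45 ± 7.76 in the wild type (SD, n = 3 each), a log2 change of 4.53 ± 0.55 (limma adjusted p = 0.00485). PDE_09675 stood at 255 ± 25.1 against 39.6 ± 9.01 FPKM, a log2 change of 2.67 ± 0.23 (limma adjusted p = 0.00114). PDE_03292 stood at 13.4 ± 1.82 against 251 ± 81.5 FPKM, a log2 change of -4.09 ± 0.27 (limma adjusted p = 0.000156). PDE_03279 stood at 3.64 ± 0.590 against 249 ± 202 FPKM, a log2 change of -4.89 ± 0.95 (limma adjusted p = 0.0438). The wild-type values of PDE_03279 were 330, 18.4 and 397 FPKM in replicates 1, 2 and 3, and under 13 of 24 other settings it was no longer past the threshold. Of the 143 genes called, 87 were also called in the deletion strain against the wild type, 29 with the same sign and 58 with the opposite sign. A fit to these 2 strains alone gave 199 higher and 91 lower. The count also moved with the 2 libraries that stood apart. Without wild-type replicate 2 it was 248 higher and 435 lower, without deletion replicate 2, which enters through the shared spread, 272 higher and 151 lower, and without both 1418 higher and 1126 lower. Without wild-type replicate 1 it was 26 higher and 31 lower, and without wild-type replicate 3 it was 26 and 20. Without recovery replicates 1, 2 and 3 in turn it was 15 and 17, 14 and 17, and 40 and 42, and without deletion replicate 3 it was 53 and 41.

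**Figure D3:**
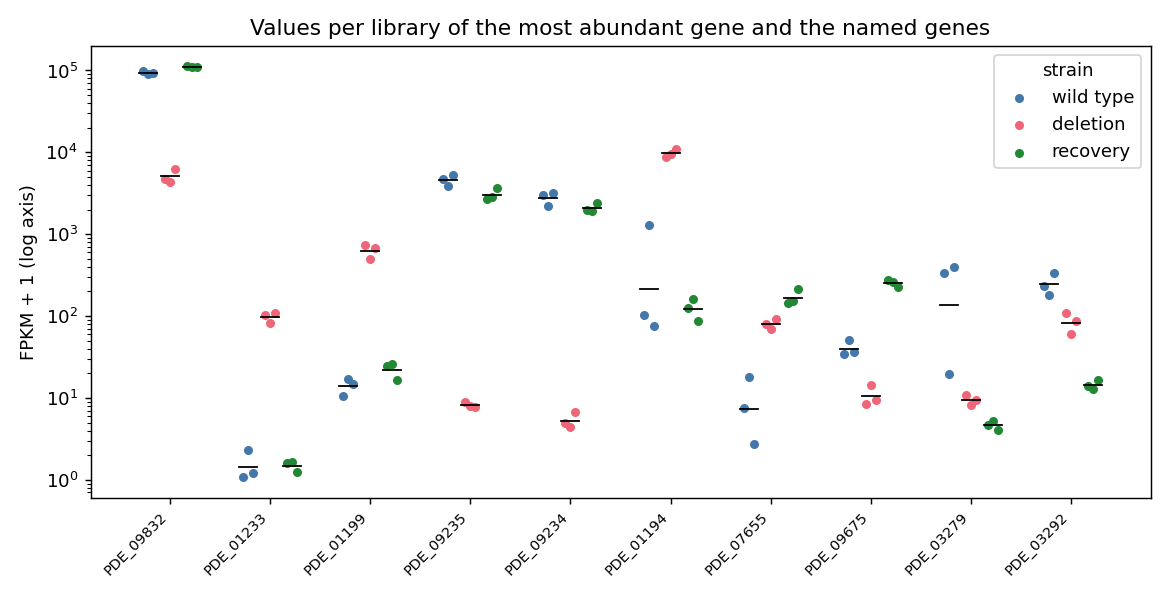
FPKM + 1 on a log axis of the most abundant gene, PDE_09832, and of the genes named by the rule, with 1 point per library, coloured by strain, and a bar at the mean of the log values of each strain. PDE_09235 lies between 3865 and 5331 FPKM in the wild type and between 6.82 and 7.87 in the deletion strain, and wild-type replicate 2 lies apart from the other wild-type libraries in PDE_01194 and PDE_03279.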

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

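The settings that leave out both wild-type replicate 2 and deletion replicate 2, that use array weights, or that drop the most abundant gene were chosen after seeing the data, as were the tests of other splits. Pseudocounts, filters, rescaling to TPM, quantile normalization, median centring, limma without trend and robust options, and leaving out the most abundant gene moved no count of calls by more than 1.5 times and the share of higher calls by no more than 10 percentage points. The balance of higher and lower calls still turned with the scaling. Deletion against recovery, with 1402 higher and 1462 lower, had 1635 and 1187 after rescaling to TPM, 1638 and 1329 after quantile normalization, 1610 and 1308 after median centring, and 1214 and 1640 without the most abundant gene. Recovery against wild type turned to 56 and 71 after median centring and 79 and 85 after quantile normalization, and deletion against both turned to 866 and 905 without the most abundant gene. Of 286 values of named genes over all settings, 273 kept their direction and their side of the threshold, 0 reversed and 13 were no longer past it. All 13 belonged to PDE_03279 in recovery against wild type, with log2 changes from -4.98 to -4.09 in those settings and adjusted p in limma from 0.0438, where the threshold was 0.01, to 0.194. PDE_01233 was not tested without both libraries that stood apart. The gene list alternatives were not run, because no gene was named.

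Counts below are higher then lower, in the order deletion against wild type, deletion against recovery, recovery against wild type, and deletion against both. An adjusted p under 0.01 left 642 and 604, 748 and 824, 24 and 25, and 509 and 526. Testing against a 1.5-fold change left 328 and 444, 438 and 521, 16 and 17, and 266 and 380. Both settings are stricter by construction. Fitting only the strains compared gave 760 and 680 in the first and 199 and 91 in the third, and the cause was not tested. Array weights gave 2448 and 2205, 2389 and 2696, 2484 and 1548, and 1842 and 1760. Leaving out both libraries that stood apart gave 2599 and 2319, 2645 and 2809, 1418 and 1126, and 1993 and 1861. Of the 143 genes called in recovery against wild type, 142 were called without both libraries and 143 with array weights, with the same sign.

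Leaving out 1 library at a time gave 785 to 2155 higher and 649 to 1601 lower in deletion against wild type. It gave 883 to 2063 higher and 916 to 2234 lower in deletion against recovery, 14 to 272 higher and 17 to 435 lower in recovery against wild type, and 667 to 1689 higher and 606 to 1424 lower against both. Each highest count came without deletion replicate 2, except the 435, which came without wild-type replicate 2. The lowest came without wild-type replicate 1 (785), wild-type replicate 3 (649, 667 and 606), recovery replicate 2 (883 and 14), or recovery replicate 1 (916 and 17, the latter also without recovery replicate 2).

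The replicate numbers were not taken to pair the samples, since 3 of 9 same-number pairs had deviations correlated over 0.1 (range -0.106 to 0.222). Of 9 samples 6 samples had their highest correlation with a library of their own number, and 1 in both other strains. With the replicate number as a block the counts were 1154 and 987, 1295 and 1387, 54 and 59, and 897 and 823.

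Of the 10 splits of the 6 libraries in each comparison, only the real one (1 of 10) gave as many genes, with 2374 against at most 55 in deletion against wild type, 2864 against at most 0 in deletion against recovery, and 143 against at most 5 in recovery against wild type. With 10 splits the share is never under 0.1, too few for a threshold of 0.05. For deletion against both, only the real split of the 9 libraries (1 of 100, the lowest possible) gave as many, 1879. The 1 other keeping the deletion libraries together gave 1566, the rest at most 18. Chance is argued against only for that grouping. Limits set by absolute depth, which is unknown, were not estimated.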

Other observations

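All tests in this part were chosen after the results were seen, and locus numbers named here were chosen after their values were seen.

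Genes that changed in the deletion strain lay close together along the locus numbers. Of the genes called with at least 2-fold change against both other strains, 560 were lower and 498 higher. Among the lower genes 177 neighbouring pairs were found in the order of tested genes, where random placement gave a mean of 34.4 and at most 58. Among the higher genes there were 107 pairs against a mean of 27.2 and at most 45. In 10000 permutations each p was 0.0001, the smallest they can give. The lower genes held 8 runs of 5 or more, with 88 genes, and the higher genes 4 such runs, with 27. The longest run, PDE_00789 to PDE_00811, held 23 genes with a median log2 change of -4.84 against the wild type, and the median of its genes was 295 FPKM in the wild type, 10.3 in the deletion strain and 382 in the recovery strain. The run PDE_09227 to PDE_09245, which includes both named genes with the steepest falls, held 19 genes with a median log2 change of -8.19. It took 3.09% ± 0.612 of summed FPKM in the wild type, 0.0312% ± 0.00767 in the deletion strain and 2.29% ± 0.205 in the recovery strain (SD, n = 3). The longest higher run, PDE_01228 to PDE_01238, held 10 tested genes with a median log2 change of 2.98.

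Random placement of the called genes along the numbers is argued against by the permutation p of 0.0001. A stretch of DNA missing from the deletion strain, with stray reads from the other libraries, would leave its genes no higher than stray reads reach, and the lowest ratio to the other strains among abundant genes, at most 0.157% in any deletion library, is an upper bound on these. In 2 of the 4 runs of 12 or more lower genes, all 35 genes lay over 3 times that bound in all 3 deletion libraries, which argues against a missing stretch there. In PDE_01063 to PDE_01076 10 of 13 did and in PDE_09227 to PDE_09245 8 of 19. The test says nothing about the remaining genes, since genes of PDE_09227 to PDE_09245 themselves had the lowest ratio in all 3 deletion libraries. In the recovery strain the median gene of that run stood at 899 FPKM against 1327 in the wild type, and that of PDE_01063 to PDE_01076 at 72.6 against 69.0, with 0 genes of either called. That goes against a missing stretch if the recovery strain was made from the deletion strain, which the labels do not state, so the explanation stays open for these genes. A hypothesis is that these runs are clusters of neighbouring genes that may be expressed together and depend on crzA. The file gives no positions, so whether consecutive numbers are neighbours on a chromosome was not tested.

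Wild-type replicate 2 stood apart from its own group: 740 genes differed at least 2-fold in one direction from both replicates 1 and 3, 190 higher and 550 lower. Such genes numbered 890 for deletion replicate 2 and from 10 to 78 for each of the other 7 libraries. Its relative depth was estimated at 1.21% from that of replicates 1 and 3, but the estimate could not have shown a 2-fold difference. Values of a library at 2-fold lower depth are also whole multiples of the same step. Over the 179 abundant genes, the median dispersion was at least 62.8 between replicates 1 and 2 and 46.2 between 2 and 3. Between replicates 1 and 3 it was at least 3.22. Read sampling at 2-fold lower depth would not reach the first 2 values, which argues against depth as the cause in abundant genes. For low genes depth was not settled. A single mixture with RNA of the other strains is argued against as the whole cause. Taking genes at least 3-fold from wild-type replicates 1 and 3 in both other strains, the 11 higher genes implied a median share of 0.379 (interquartile range 0.293 to 0.606), and the 42 lower genes 1.02 (0.937 to 1.08). Partial mixing stays open. Of the 740 genes, 7.43% lay over 1.5-fold outside the range of all other libraries. For the other libraries this share of their own such genes was 8.57% to 57.7%. A difference in culture or sequencing batch that the labels do not give stays open: the deviations of replicate 2 correlated at 0.126 between wild type and deletion, 0.117 between wild type and recovery and -0.0237 between deletion and recovery. Differences in growth between cultures of one strain were not tested.

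In 8 genes every deletion library was under 0.5 FPKM and all 6 other libraries were at 10 or more. Of these, PDE_01071, PDE_01073, PDE_01074 and PDE_01076 lie in the run PDE_01063 to PDE_01076, and PDE_01430 in the run PDE_01429 to PDE_01433. In 7 of the 8 genes the recovery strain was not called against the wild type, which does not show equal levels. The recovery means of these 7 were 0.719 to 1.57 times the wild-type means. The exception was PDE_02584, at 26.5 ± 3.75 FPKM in the wild type, 0.0900 ± 0.0656 in the deletion strain and 170.2 ± 6.44 in the recovery strain (SD, n = 3), where the recovery mean was 6.41 times the wild-type mean (limma adjusted p = 4.66e-05). Genes called against the wild type in both the deletion and the recovery strain were also sorted by direction. Of these, 20 were at least 2-fold lower in the deletion strain and at least 2-fold higher in the recovery strain, and 14 were the reverse. The file names none of these genes.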
